A study of Homo sapiens with 5 samples.

How the data were processed

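THP-1 cells that expressed Cas9 were transduced with a pooled sgRNA library at a multiplicity of infection near 0.3, and live GFP-positive cells were sorted 12 days later, per the labels. They were stained with tagged antibodies to CD11b and CD16 and captured with a 5' single-cell immune profiling kit. The 5 libraries listed for the series were 1 of antibody tags, 3 of cDNA and 1 of sgRNAs, all from the same capture, and they were not separable in the matrices. The unit of all values used was counts: the deposited matrices held whole-number UMI counts of 33538 genes with 4 antibody tags, and of the same genes with 45 sgRNAs, for 8091 barcodes. Gene counts of both matrices were identical. Per the file headers the matrices came from Cell Ranger 3.1.0, and the submitters' processing notes name Cell Ranger, Seurat 3.1.3 and the build GRCh38. The rule that chose the barcodes is not given in the sources used here. The labels name CD11b and CD16 only, so the report uses these 2 tags, and tags for CD15 and CD14 found in the matrices are treated with the additional observations. All columns of the deposited files matched the pooled sample, with 0 left unmatched.

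Cells were kept with at least 500 detected genes and at most 15% mitochondrial UMIs, which left 5038 barcodes (62.3%). A cell was given a guide where its top sgRNA had at least 5 UMIs and at least 80% of its sgRNA UMIs, which held for 2318 cells. Of the cells that passed the first filters, 1704 had a top guide under 5 UMIs, and 351 had 2 or more guides with at least 20% each. The dominance rule left out such cells, doublets among them, and no doublet caller was run. Guides with fewer than 15 cells were not used. No usable guide remained for MYB, and 1 remained for GFI1B, which is given as values. Median RNA UMIs per assigned cell were 13888. Guides whose names begin with Non-Targeting or Rosa26 were controls. They were numbered control replicate 1 to 4 for non-targeting guides 6, 17, 18 and 19, and 5 and 6 for Rosa26 guides 1 and 2. Replicate numbers of targeting guides were those in the feature names, except for MED23, whose replicates 1 and 2 were its guides 2 and 3, and ZFP36L2, whose replicates 3 and 5 were guides 2 and 5 of a set named after its zinc-finger domain.

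RNA counts were summed over the cells of each guide and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM factors, filterByExpr by target). All 35 guides entered 1 fit with 21 residual degrees of freedom, and each target was set against the 6 control guides. Adjusted p-values are Benjamini-Hochberg values of this test unless another is named, with a threshold of 0.05, over 10282 genes. Levels are CPM of the summed guide, and log2 changes carry ± 1 SE. The biological coefficient of variation between guides was 12.9%. Gene lists (25, fixed before the data were examined) were tested with camera in limma 3.58.1 with a preset correlation of 0.01 on voom values, with an estimated correlation beside it (the camera adjusted p given) and with fry, adjusted over the lists of a target. Members of a list count as having risen or fallen at adjusted p under 0.05 over all genes, and separately when adjusted over the list alone. The lists whose members are named were picked after the list results were seen.

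Genes named followed a rule fixed beforehand. For ZFP36L2 these were the targeted gene, ITGAM, FCGR3A and the 10 largest rises and 10 largest falls among genes past the threshold, with a mean log2 CPM above 3 and the same direction in every guide. For other targets the 3 largest of each kind were taken, and from each list up to 4 members with the smallest p. The report names these in part, chosen for length after their values were seen. ZFP36L1, FUT4, FUT7 and CD14 RNA in ZFP36L2 guides and ZFP36L2 RNA in other guides, with ZFP36L1 and CD14 RNA where they passed, were added after the data were seen, and ZFP36L1 and CD14 stand in fixed lists. Gene names and identifiers are those of the files. Positions are from a RefSeq gene table of the assembly GRCh38.p14. Fitted folds of genes with a few UMIs depend on the prior count, so FCGR3A is given as counts. Where leaving out 1 guide ended a call, the adjusted p without it is given, or its range for genes named without values, with the log2 change where the fold moved by over 1.5 times, and with 1 guide left this also reflects fewer guides.

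Antibody signal was the mean UMIs per cell of a guide, compared on the log2 scale by two-sided exact permutation of guides, with Benjamini-Hochberg adjustment over 12 targets and both antibodies. Correlations used 100000 resamples. Analyses of antibody tags used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The gene test was tested on simulated data in 5 draws of 200 changed genes. With 3 guides as for ZFP36L2 it recovered 69.8% of 2-fold and 89.2% of 4-fold changes, and 5.10% of calls were false. With 2 guides as for MED24 it recovered 25.4% and 53.6%, with 2.90% false. A first single draw had a higher false share, and the draws were then extended to 5 with that draw included. Responses were compared over 20 simulations of unchanged guides and 20 splits of the control guides into 3 and 3.

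Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, assignment at 3 UMIs and 60% or 10 UMIs and 90%, no cell filter, no cells in the top 5% of RNA UMIs, only the guides of the target and the controls, all other guides as comparator, and each guide left out in turn. For antibodies they included the mean of log2(UMIs + 1), UMIs per 10000 RNA UMIs and the 90th and 99th percentiles for high CD11b. Chosen after seeing the data were non-targeting or Rosa26 controls alone, cells with 10000 to 20000 RNA UMIs, medians over cells, values capped at the 99th percentile and the CD15 and CD14 tags. Guide sequences, cutting positions and indel rates were not used here.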

Results

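The data came from a pooled CRISPR screen read out in single cells by ECCITE-seq, a method that records the RNA, the surface antibody tags and the sgRNA of each cell. The cells were THP-1, a human monocytic acute myeloid leukaemia line that expressed Cas9, harvested on day 12 after transduction. The series title names ZFP36L2, an RNA-binding protein that promotes decay of transcripts with AU-rich elements, and differentiation of acute myeloid leukaemia. The comparisons therefore asked which RNAs and which of the maturation antigens CD11b and CD16 differed between cells with a guide against a candidate gene and cells with a control guide. One capture of 1 pooled culture gave 8091 barcodes with 89602663 RNA UMIs in all. After filters on genes and mitochondrial share, 5038 cells remained, and 2318 of them could be given 1 guide. Guides with at least 15 cells numbered 35 and held 2275 cells. They comprised 6 control guides (4 non-targeting and 2 against Rosa26), 28 guides against 12 genes with 2 or 3 guides each, and 1 guide against GFI1B. Summed RNA UMIs per guide ranged from 135276 to 2726451. Median RNA UMIs per cell ran from 10967.5 to 15155 in control guides, and every guide of ZFP36L2 (17399 to 20659), FLI1 (15473.5 to 18390) and EP300 (21510 to 26374.5) lay above these, every STK11 guide (6889 to 10289) below. Cells of like depth were compared for ZFP36L2 alone. The guide was the unit of spread, so all p-values measure the spread between guides within 1 culture and 1 capture, which may be partly technical.

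In guides labelled ZFP36L2, genes of the lysosome, of the NADPH oxidase and of glycolysis rose against the control guides. Monocyte and macrophage genes were called higher and leukaemic progenitor genes lower as lists, but both calls were lost with an estimated correlation (adjusted p = 0.0794 and 0.162). Of 10282 genes tested, 735 passed the threshold, of which 478 rose and 257 fell. The targeted gene itself, ZFP36L2 (ENSG00000152518, chromosome 2, 43222402 to 43226606), was higher, at 727 ± 74.3 CPM (SD, n = 3) against 468 ± 52.9 CPM (SD, n = 6) in control guides, a log2 change of 0.63 ± 0.145 (edgeR quasi-likelihood test, adjusted p = 0.00602). Small insertions and deletions made by Cas9 need not lower the RNA of the gene they hit, so this level gave no check of the guide labels. The call was lost against the 2 Rosa26 guides alone (log2 change 0.58, adjusted p = 0.115) and in cells with 10000 to 20000 RNA UMIs (0.42, adjusted p = 0.202), both chosen after seeing the data. Among the control guides, non-targeting guide 17 stood apart at 369 CPM. ITGAM, which encodes CD11b, rose from 26.6 ± 6.86 (SD, n = 6) to 48.3 ± 9.44 CPM (SD, n = 3), a log2 change of 0.76 ± 0.222 (adjusted p = 0.0284). FCGR3A, which encodes CD16, had 8 UMIs over the 3 ZFP36L2 guides and 1 UMI over the 6 control guides. Without ZFP36L2 replicate 2, adjusted p was 0.242 for ITGAM. Leaving out ZFP36L2 replicate 3 gave adjusted p of 0.0861 for ITGAM. With ZFP36L2 replicate 5 left out, adjusted p was 0.0595 for ZFP36L2. ITGAM reached adjusted p of 0.0718 without control replicate 6.

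The 10 largest rises with ZFP36L2 guides included LYZ, the secreted lysozyme, from 76 to 313 CPM (log2 change 1.95 ± 0.472, adjusted p = 0.00845), SPP1, the cytokine osteopontin (1.95 ± 0.419, adjusted p = 0.00302), MPEG1, the pore-forming perforin-2 of macrophages (2.53 ± 0.583, adjusted p = 0.00570), and GPNMB, a lysosomal membrane glycoprotein (from 13.7 to 54.3 CPM, adjusted p = 0.0207). JAML, an adhesion receptor of leukocytes, rose by 2.33 ± 0.329 (adjusted p = 2.6e-05), and ERRFI1, an inhibitor of EGF receptor signalling, by 2.14 ± 0.274 (adjusted p = 5.86e-06). The other rises were AKR1C2, an aldo-keto reductase (3.66 ± 0.761, adjusted p = 0.00243), the peptide hormone ADM (2.19 ± 0.557, adjusted p = 0.0121), the oxygen-sensing prolyl hydroxylase EGLN3 (2.00 ± 0.480, adjusted p = 0.00796) and HMOX1, which degrades haem (1.90 ± 0.480, adjusted p = 0.0117). Single control guides stood apart for EGLN3 and HMOX1 (values below). Dropping ZFP36L2 replicate 2 gave adjusted p of 0.337 for AKR1C2 (log2 1.94), 0.427 for GPNMB (log2 1.18), 0.0989 for LYZ and 0.304 for HMOX1 (log2 1.27). Omitting ZFP36L2 replicate 3 gave adjusted p of 0.311 for MPEG1 (log2 1.21), 0.0591 for ADM, 0.0693 for EGLN3 and 0.0543 for GPNMB. Removing ZFP36L2 replicate 5 gave adjusted p of 0.0899 for EGLN3. GPNMB reached adjusted p of 0.0602 without control replicate 5.

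Of the 10 largest falls, CBFA2T3, a corepressor of blood stem and progenitor cells, went from 31.5 to 8.84 CPM (log2 change -1.72 ± 0.328, adjusted p = 0.00102), WT1, a transcription factor of leukaemic blasts, changed by -1.58 ± 0.347 (adjusted p = 0.00367), and ID3, an inhibitor of helix-loop-helix factors, by -1.90 ± 0.524 (adjusted p = 0.0206). The receptor tyrosine kinase EPHB1 (-1.86 ± 0.340, adjusted p = 0.000742), the imprinted gene MEST (-1.69 ± 0.377, adjusted p = 0.00440), RHEX, a signalling protein of erythroid expansion (-2.08 ± 0.587, adjusted p = 0.0240), and the annexin ANXA8 (-1.91 ± 0.451, adjusted p = 0.00672) also fell. The last 3 were the cap methyltransferase CMTR2 (-1.61 ± 0.376, adjusted p = 0.00641) and the ankyrin repeat genes ANKRD18A (-2.56 ± 0.558, adjusted p = 0.00361) and ANKRD36B (-1.62 ± 0.411, adjusted p = 0.0121). For ANKRD18A, non-targeting guide 17 stood apart at 23.4 CPM. When ZFP36L2 replicate 2 was omitted, adjusted p was 0.0521 for RHEX (log2 -2.83), 0.0575 for ANXA8, 0.175 for ID3 and 0.0545 for CMTR2. Without ZFP36L2 replicate 3, adjusted p was 0.0673 for RHEX, 0.0575 for ID3 and 0.0537 for ANKRD36B. Leaving out ZFP36L2 replicate 5 gave adjusted p of 0.0515 for ANKRD18A (log2 -1.95), 0.168 for RHEX, 0.0734 for ANXA8, 0.0501 for ID3 and 0.0822 for ANKRD36B. Calls held with folds moved over 1.5 times without ZFP36L2 replicate 2 (ANKRD18A 0 UMIs).

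**Figure D1:**
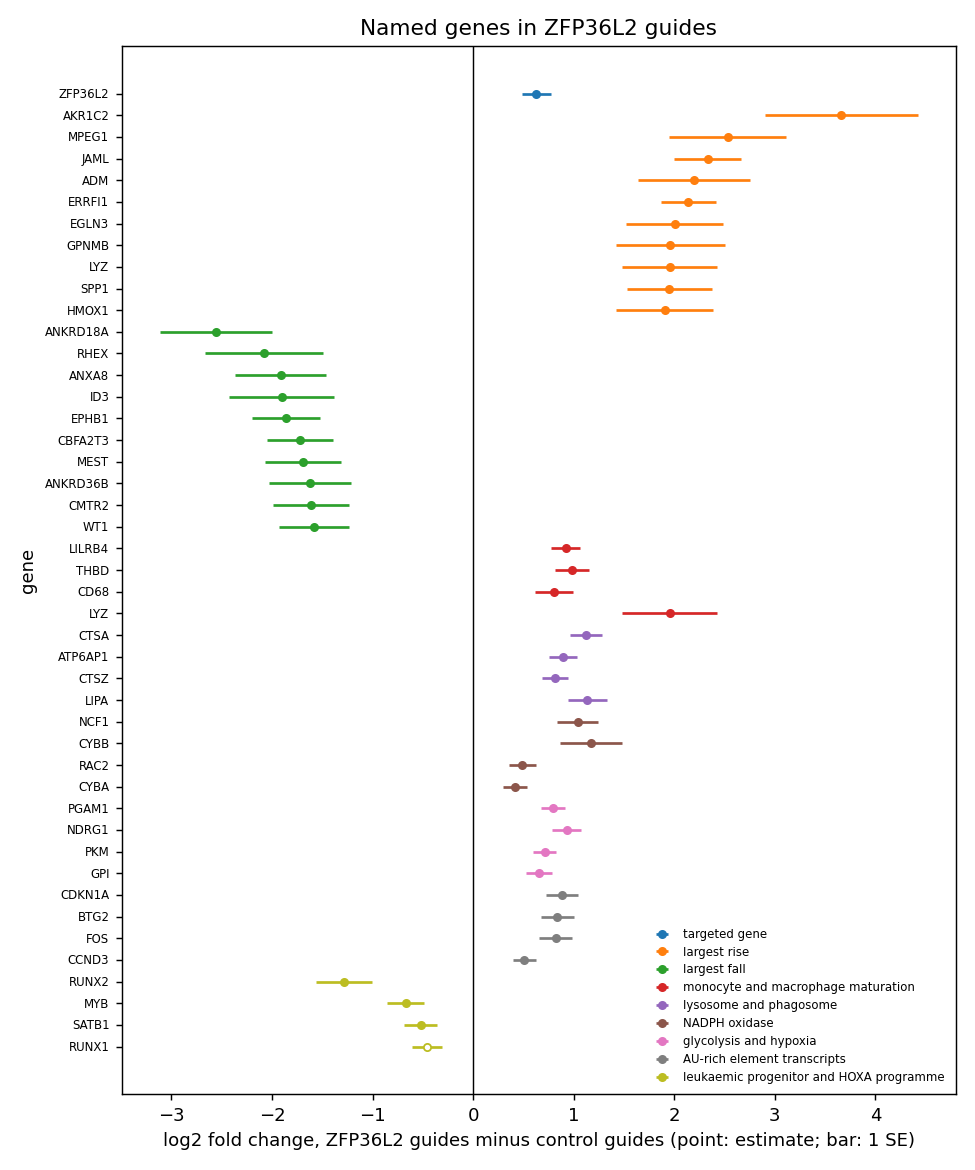
Log2 fold change of genes named for ZFP36L2 guides (x axis) for the 3 guides against the 6 control guides, with points for estimates, bars for 1 SE, filled points for genes past adjusted p 0.05 and an open point for RUNX1, which did not pass. ZFP36L2 itself lies at 0.63, and colours give the largest changes and 6 gene lists, LYZ standing under 2 of them.

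Gene lists fixed before the data were examined were tested next. Of the lysosome and phagosome genes, 18 of 36 rose over all genes and 25 over the list alone (camera adjusted p = 0.0433, with an estimated correlation here and below). Examples were the protease CTSA (1.12 ± 0.158, adjusted p = 2.6e-05), the cathepsin CTSZ (0.82 ± 0.132, adjusted p = 0.000181), the lipase LIPA (1.14 ± 0.196, adjusted p = 0.000407) and the proton pump subunit ATP6AP1 (0.89 ± 0.141, adjusted p = 0.000126). Of the NADPH oxidase, which makes superoxide in phagocytes, 4 of 7 rose over all genes and 4 over the list alone (camera adjusted p = 0.0144), namely NCF1 (1.04 ± 0.204), CYBB (1.17 ± 0.307), RAC2 (0.49 ± 0.134) and CYBA (0.42 ± 0.119). Of the monocyte and macrophage maturation genes, 13 of 41 rose over all genes and 19 over the list alone, a call lost at camera adjusted p = 0.0794. They included the inhibitory receptor LILRB4 (0.92 ± 0.144, adjusted p = 0.000125), thrombomodulin THBD (0.99 ± 0.170, adjusted p = 0.000407) and the endosomal glycoprotein CD68 (0.81 ± 0.189, adjusted p = 0.00641). Of the AU-rich element transcripts, 13 of 48 rose over all genes and 18 over the list alone (camera adjusted p = 0.0433), among them the cell-cycle inhibitor CDKN1A (0.88 ± 0.159, adjusted p = 0.000666), the antiproliferative gene BTG2 (0.84 ± 0.162, adjusted p = 0.00114), the immediate-early factor FOS (0.82 ± 0.164, adjusted p = 0.00166) and the cyclin CCND3 (0.51 ± 0.112, adjusted p = 0.00376). With ZFP36L2 replicate 2 left out, adjusted p was 0.123 for CYBB, 0.0710 for RAC2, 0.0657 for CYBA and 0.102 for CD68. Dropping ZFP36L2 replicate 3 gave adjusted p of 0.0653 for CYBB, 0.0873 for RAC2 and 0.0509 for CYBA. Omitting ZFP36L2 replicate 5 gave adjusted p of 0.0596 for RAC2 and 0.154 for CYBA.

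Of the glycolysis and hypoxia genes, 16 of 29 rose over all genes and 20 over the list alone (camera adjusted p = 0.00454), including the enzymes PGAM1 (0.79 ± 0.118, adjusted p = 5.58e-05), PKM (0.71 ± 0.114, adjusted p = 0.000159) and GPI (0.65 ± 0.127, adjusted p = 0.00120) and the hypoxia-induced gene NDRG1 (0.93 ± 0.140, adjusted p = 6.29e-05). Of the nuclear-encoded oxidative phosphorylation genes, 7 of 55 rose over all genes and 18 over the list alone, a call lost at camera adjusted p = 0.0794, and examples were cytochrome c1 CYC1 (0.65 ± 0.137, adjusted p = 0.00242) and the ATP synthase subunit ATP5F1B (0.54 ± 0.123, adjusted p = 0.00544). Of the unfolded protein and ATF4 genes, 6 of 28 rose over all genes and 7 over the list alone, a call lost at camera adjusted p = 0.0743, with the disulphide isomerase PDIA3 at 0.73 ± 0.124 (adjusted p = 0.000332). Smaller groups also passed the list test and lost the call with an estimated correlation. Of the integrins and adhesion genes, 4 of 19 rose over all genes and 6 over the list alone (camera adjusted p = 0.217), with the beta chain ITGB2, the partner of ITGAM, at 0.77 ± 0.205 (adjusted p = 0.0164). Of the MHC class II genes, 2 of 9 rose over all genes and 6 over the list alone (camera adjusted p = 0.327), the peptide exchange factor HLA-DMA (1.26 ± 0.282, adjusted p = 0.00438) and HLA-DRB1 (1.03 ± 0.272, adjusted p = 0.0155). HLA-DRB1 stood at -0.03 against all other guides. Of the NF-kB genes, 2 of 25 rose over all genes and 5 over the list alone (camera adjusted p = 0.162), the chemokines CCL3 (1.44 ± 0.389, adjusted p = 0.0186) and CCL2 (1.88 ± 0.524, adjusted p = 0.0219). Removing ZFP36L2 replicate 2 gave adjusted p of 0.0873 for ITGB2, 0.0765 for HLA-DMA, 0.0834 for HLA-DRB1, 0.0800 for CCL3 and 0.337 for CCL2 (log2 1.18). When ZFP36L2 replicate 3 was omitted, adjusted p was 0.0864 for HLA-DRB1. Without ZFP36L2 replicate 5, adjusted p was 0.0558 for ITGB2, 0.112 for CCL3 and 0.0714 for CCL2. CCL2 reached adjusted p of 0.0504 and 0.0590 without control replicate 4 and 5.

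Fewer lists were called lower. Of the leukaemic progenitor and HOXA genes, 3 of 21 fell over all genes and 7 over the list alone, a call lost at camera adjusted p = 0.162. These were the transcription factors RUNX2 (-1.29 ± 0.279, adjusted p = 0.00329) and MYB (-0.67 ± 0.188, adjusted p = 0.0232) and the chromatin organiser SATB1 (-0.52 ± 0.166, adjusted p = 0.0468), while RUNX1 stood at -0.46 ± 0.148 (adjusted p = 0.0505). Of the G2 and M phase genes, 2 of 53 fell over all genes and 1 over the list alone (camera adjusted p = 0.689), the heterochromatin protein CBX5 (-0.54 ± 0.144, adjusted p = 0.0160) and the condensin subunit SMC4 (-0.54 ± 0.165, adjusted p = 0.0370). No S phase gene of 41 passed, although the list test called the group lower (camera adjusted p = 0.439), and the cytosolic ribosomal protein list was likewise called lower with 0 of 74 members past the threshold (camera adjusted p = 0.668). The interferon list (1 of 40 rose and 0 over the list alone, camera adjusted p = 0.668) and the MHC class I list (0 of 19, camera adjusted p = 0.462) were called higher. Leaving out ZFP36L2 replicate 2 gave adjusted p of 0.186 for SATB1, 0.0905 for CBX5 and 0.188 for SMC4. With ZFP36L2 replicate 3 left out, adjusted p was 0.0554 for MYB, 0.132 for SATB1, 0.0850 for CBX5 and 0.130 for SMC4. Dropping ZFP36L2 replicate 5 gave adjusted p of 0.226 for MYB, 0.119 for SATB1 and 0.0667 for SMC4. SATB1 reached adjusted p of 0.0564, 0.0592, 0.0764, 0.0794 and 0.0955 without control replicate 1, 2, 4, 5 and 6. SMC4 reached adjusted p of 0.0595, 0.0927 and 0.0664 without control replicate 2, 4 and 6.

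The count of 735 genes with ZFP36L2 guides depended on guides and comparator. Leaving out guide replicate 2, 3 or 5 of ZFP36L2 gave 307, 424 and 344 genes. Against all other guides, those of other targets included, 131 passed, with 18 of the 64 named genes that had passed.

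**Figure D2:**
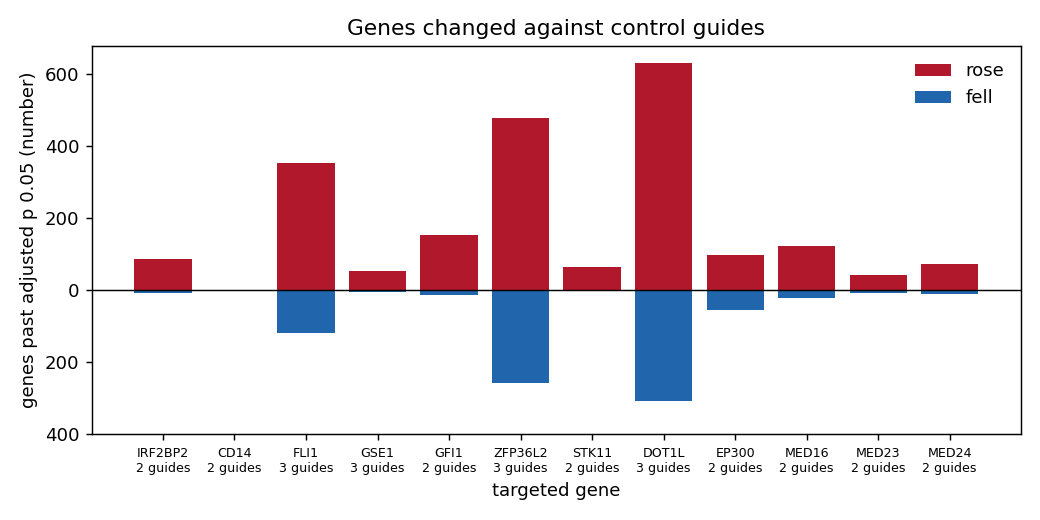
Number of genes past adjusted p 0.05 (y axis) that rose (above 0) or fell (below 0) against the 6 control guides for each of 12 targeted genes (x axis). DOT1L (632 rose, 307 fell) and ZFP36L2 (478 rose, 257 fell) had the most, and CD14 had 0.

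Guides against DOT1L, the histone H3 lysine 79 methyltransferase, gave the most changed genes, with a broad rise of monocyte genes and a fall of HOXA-programme genes. 939 genes passed, of which 632 rose and 307 fell. The targeted gene, DOT1L (ENSG00000104885, chromosome 19, 2163933 to 2232578), was at 25.5 ± 8.80 CPM (SD, n = 3) against 39.1 ± 9.58 CPM (SD, n = 6) in control guides (log2 change -0.75 ± 0.299, adjusted p = 0.118). Of the monocyte and macrophage maturation genes, 32 of 41 rose over all genes and 34 over the list alone (camera adjusted p = 0.00921). They included the calcium-binding alarmins S100A12 (5.31 ± 0.590, adjusted p = 9.05e-08) and S100A8 (2.97 ± 0.432, adjusted p = 1.02e-05), LYZ from 76 to 1412 CPM (4.06 ± 0.483, adjusted p = 3.45e-07), the nuclear protein MNDA (1.63 ± 0.230, adjusted p = 6.37e-06) and ITGAM (1.77 ± 0.265, adjusted p = 1.54e-05). FCGR3A had 13 UMIs over 3 guides. Of the progenitor and HOXA genes, 10 of 21 fell over all genes and 12 over the list alone (camera adjusted p = 0.0133), with the kinase CDK6 (-1.51 ± 0.182, adjusted p = 3.95e-07), SATB1 (-1.52 ± 0.222, adjusted p = 1.09e-05), HOXA11 (-3.17 ± 0.495, adjusted p = 2.55e-05) and the RNA-binding protein IGF2BP2 (-1.37 ± 0.234, adjusted p = 9.04e-05). One member of that list rose.

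Inflammatory genes rose with DOT1L guides too. Of the AU-rich element transcripts, 22 of 48 rose over all genes and 25 over the list alone (camera adjusted p = 0.0135), and of the NF-kB genes, 11 of 25 rose over all genes and 13 over the list alone (camera adjusted p = 0.0380). The monocyte attractant CCL2 changed by 4.09 ± 0.525 (adjusted p = 1.45e-06), the neutrophil attractant CXCL8 by 3.95 ± 0.523 (adjusted p = 3.01e-06), the AP-1 subunit JUN by 1.83 ± 0.283 (adjusted p = 2.22e-05), CCL3 by 2.42 ± 0.475 (adjusted p = 0.000528) and the apoptosis inhibitor BCL2A1 by 2.61 ± 0.527 (adjusted p = 0.000777). Of the glycolysis and hypoxia genes, 11 of 29 rose over all genes and 11 over the list alone (camera adjusted p = 0.0252), with the glucose transporter SLC2A3 from 4.99 to 64.2 CPM (adjusted p = 2.74e-07) and PKM at 0.98 ± 0.117 (adjusted p = 3.57e-07). Of the MAPK feedback genes, 5 of 15 rose over all genes and 5 over the list alone (camera adjusted p = 0.00921), with PHLDA1 at 3.39 ± 0.415 (adjusted p = 5.53e-07) and IER3 at 3.68 ± 0.646 (adjusted p = 0.000162). The largest changes were the complement subunit C1QC (5.77 ± 1.00, adjusted p = 0.000138), which had 11 UMIs in control replicate 1 and none in the other control guides, S100A12 and the protease inhibitor SERPINA1 (4.42 ± 0.399, adjusted p = 8.98e-10) upwards, and the helix-loop-helix inhibitor ID1 (-4.65 ± 1.27, adjusted p = 0.0144) and the signalling adaptor TRAF2 (-3.86 ± 0.879, adjusted p = 0.00284) downwards, together with TTC28, which had 0 UMIs in the 3 DOT1L guides and 71 in the 6 control guides (adjusted p = 0.0152). Without DOT1L replicate 1 the count fell to 256 genes. Omitting DOT1L replicate 1 gave adjusted p of 0.347 for C1QC (log2 3.74), 0.163 for TTC28, 0.199 for ID1 (log2 -3.87), 0.111 for TRAF2 (log2 -3.07), 0.142 for CCL3 and 0.151 for BCL2A1. Removing DOT1L replicate 3 gave adjusted p of 0.0704 for TTC28. Folds moved over 1.5 times with calls kept without DOT1L replicate 1 (S100A12 log2 4.16, SERPINA1 3.58, CCL2 3.33), DOT1L replicate 2 (TRAF2 0 UMIs, LYZ 3.42), DOT1L replicate 3 (C1QC 6.46, ID1 0 UMIs, TRAF2 -3.13, SATB1 -2.22, HOXA11 -4.32, IGF2BP2 -1.95), control replicate 1 (S100A12 5.91) and control replicate 4 (CXCL8 4.81, IER3 4.57).

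Guides against FLI1, an ETS-family transcription factor of blood cells, raised MHC class II genes, and the call of the interferon-response list was lost with an estimated correlation. Its cells were deeper than those of every control guide, which was not tested as a cause. 471 genes passed, of which 353 rose and 118 fell. The targeted gene, FLI1 (ENSG00000151702, chromosome 11, 128685132 to 128813267), was at 32.6 ± 4.43 CPM (SD, n = 3) against 41.5 ± 8.10 CPM (SD, n = 6) in control guides (log2 change -0.39 ± 0.167, adjusted p = 0.192). ITGAM stood at 0.34 ± 0.223 (adjusted p = 0.433), and at -0.39 against all other guides. Of the MHC class II genes, which present peptides to T cells, 9 of 9 rose over all genes and 9 over the list alone (camera adjusted p = 0.0439), led by HLA-DMA (1.87 ± 0.249, adjusted p = 8e-06), HLA-DRB1 (1.72 ± 0.259, adjusted p = 5.89e-05), HLA-DRB5 (2.02 ± 0.320, adjusted p = 0.000110) and HLA-DRA from 46.1 to 284 CPM (2.49 ± 0.477, adjusted p = 0.00126). HLA-DRB1 and HLA-DRB5 are near-identical copies whose reads could be shared. Of the interferon-response genes, 15 of 40 rose over all genes and 32 over the list alone, a call lost at camera adjusted p = 0.136, among them IFI27 from 240 to 1214 CPM (2.28 ± 0.377, adjusted p = 0.000197), IFI44L (1.52 ± 0.302, adjusted p = 0.00194), the membrane antiviral protein IFITM1 (1.33 ± 0.278, adjusted p = 0.00321) and the exonuclease ISG20 (1.78 ± 0.380, adjusted p = 0.00391). Of the glycolysis and hypoxia genes, 10 of 29 rose over all genes and 15 over the list alone (camera adjusted p = 0.0340), with PGAM1 at 0.69 ± 0.117 (adjusted p = 0.000287) and PGK1 at 0.66 ± 0.138 (adjusted p = 0.00318). Of the monocyte and macrophage genes, 14 of 41 rose over all genes and 18 over the list alone, a call lost at camera adjusted p = 0.0941, and of the lysosome genes, 15 of 36 rose over all genes and 22 over the list alone, lost at camera adjusted p = 0.0846. C1QC (4.70 ± 0.880, adjusted p = 0.00120, a fold that rests on control replicate 1, the only control guide with its UMIs) and HLA-DPB1 (2.64 ± 0.667, adjusted p = 0.0154) were among the 3 largest rises, and annexin ANXA3 (-1.97 ± 0.396, adjusted p = 0.00217), the immune regulator NLRC3 (-1.91 ± 0.338, adjusted p = 0.000477) and the calcium channel CACNA1E (-1.87 ± 0.342, adjusted p = 0.000771) were the largest falls. Leaving out FLI1 replicate 1, 2 or 3 gave 253, 163 and 250 genes, and against all other guides 21 passed. When FLI1 replicate 2 was omitted, adjusted p was 0.111 for HLA-DPB1. Without FLI1 replicate 3, adjusted p was 0.0678 for HLA-DPB1 and 0.0596 for ISG20. Kept calls had folds moved over 1.5 times without FLI1 replicate 1 (C1QC log2 3.93) and control replicate 1 (HLA-DPB1 4.32).

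Guides against GFI1, a transcriptional repressor of myeloid differentiation, raised MHC class II and monocyte genes. 166 genes passed, of which 153 rose and 13 fell. The targeted gene, GFI1 (ENSG00000162676, chromosome 1, 92473043 to 92486925), was at 49.4 ± 15 CPM (SD, n = 2) against 30.2 ± 5.08 CPM (SD, n = 6) in control guides (log2 change 0.73 ± 0.257, adjusted p = 0.170). ITGAM stood at 0.81 ± 0.294 (adjusted p = 0.195). Of the MHC class II genes, 9 of 9 rose over all genes and 9 over the list alone (camera adjusted p = 0.00436), including HLA-DRB1 from 85.9 to 503 CPM (2.47 ± 0.290, adjusted p = 8.5e-07), HLA-DQA1 (6.07 ± 0.696, adjusted p = 1.19e-06) and HLA-DPA1 (3.88 ± 0.492, adjusted p = 3.03e-06). Of the monocyte and macrophage genes, 13 of 41 rose over all genes and 24 over the list alone (camera adjusted p = 0.0325), including S100A12 from 9.67 to 363 CPM (5.00 ± 0.606, adjusted p = 1.19e-06), S100A9 (3.43 ± 0.489, adjusted p = 2.27e-05), S100A8 (3.22 ± 0.462, adjusted p = 2.47e-05) and LILRB4 (1.15 ± 0.173, adjusted p = 4.91e-05). HLA-DPB1 (4.13 ± 0.709, adjusted p = 0.000284) was among the 3 largest rises, and the largest falls were GMEB2 (-2.80 ± 0.715, adjusted p = 0.0293), the glycosyltransferase B3GNT5 (-1.98 ± 0.495, adjusted p = 0.0248) and the kinase anchor AKAP1 (-1.90 ± 0.434, adjusted p = 0.0107). With 1 guide left, whose spread was then assumed to be that of the other targets, 55 genes passed without GFI1 replicate 2 and 78 without replicate 3. Leaving out GFI1 replicate 2 gave adjusted p of 0.0694 for GMEB2 (0 UMIs left), 0.189 for B3GNT5 (log2 -2.35) and 0.432 for AKAP1 (log2 -1.33). With GFI1 replicate 3 left out, adjusted p was 0.0760 for HLA-DPA1 (log2 2.69), 0.247 for HLA-DPB1 (log2 3.16), 0.449 for GMEB2 (log2 -1.80) and 0.347 for B3GNT5 (log2 -1.66). Calls held with folds moved over 1.5 times without GFI1 replicate 2 (HLA-DPA1 log2 4.50), GFI1 replicate 3 (AKAP1 -2.97, HLA-DQA1 5.37) and control replicate 1 (S100A12 5.60, HLA-DPB1 5.80, HLA-DPA1 4.48).

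Guides against GSE1, a subunit of a histone deacetylase and demethylase complex, raised a few monocyte genes strongly. 57 genes passed, of which 53 rose and 4 fell. The targeted gene, GSE1 (ENSG00000131149, chromosome 16, 85169512 to 85676200), was at 56.6 ± 2.66 CPM (SD, n = 3) against 75.9 ± 11.5 CPM (SD, n = 6) in control guides (log2 change -0.44 ± 0.152, adjusted p = 0.313). The calprotectin genes S100A8 from 502 to 5428 CPM (3.44 ± 0.430, adjusted p = 4.01e-06) and S100A9 from 441 to 5693 CPM (3.68 ± 0.456, adjusted p = 4.01e-06) and the related S100A12 from 9.67 to 529 CPM (5.54 ± 0.540, adjusted p = 1.87e-08) were the 3 largest rises, and ITGAM rose from 26.6 to 66.7 CPM (1.23 ± 0.197, adjusted p = 0.000398). Of the monocyte and macrophage genes, 6 of 41 rose over all genes and 10 over the list alone, a call lost at camera adjusted p = 0.0882. The largest falls were the cystine transporter SLC7A11 (-1.74 ± 0.430, adjusted p = 0.0475), the actin-binding protein PALLD (-1.72 ± 0.365, adjusted p = 0.0127) and lactoperoxidase LPO (-1.71 ± 0.373, adjusted p = 0.0168). Leaving out GSE1 replicate 1, 2 or 3 gave 19, 40 and 30 genes. Dropping GSE1 replicate 1 gave adjusted p of 0.322 for SLC7A11, 0.142 for PALLD and 0.170 for LPO. Omitting GSE1 replicate 2 gave adjusted p of 0.0950 for SLC7A11. Removing GSE1 replicate 3 gave adjusted p of 0.286 for SLC7A11, 0.122 for PALLD and 0.190 for LPO. SLC7A11 reached adjusted p of 0.0582, 0.0790, 0.155 and 0.149 without control replicate 1, 2, 4 and 6. PALLD reached adjusted p of 0.0582 without control replicate 1 and LPO 0.0611 without control replicate 6. Folds moved over 1.5 times with calls kept without control replicate 1 (S100A12 log2 6.13).

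Guides against IRF2BP2, a transcriptional corepressor, raised MHC class II and NADPH oxidase genes, and each of the 13 calls named by the rule was lost without 1 of its 2 guides. 93 genes passed, of which 87 rose and 6 fell. The targeted gene, IRF2BP2 (ENSG00000168264, chromosome 1, 234604269 to 234610178), was at 410 ± 6.58 CPM (SD, n = 2) against 370 ± 26.7 CPM (SD, n = 6) in control guides (log2 change 0.14 ± 0.163, adjusted p = 0.848). ITGAM stood at 0.22 ± 0.359 (adjusted p = 0.915), and at -0.49 against all other guides. Of the MHC class II genes, 5 of 9 rose over all genes and 9 over the list alone (camera adjusted p = 0.0410), including HLA-DRB1 (1.99 ± 0.309, adjusted p = 0.000640) and HLA-DRA (2.71 ± 0.568, adjusted p = 0.0137). Of the NADPH oxidase genes, 3 of 7 rose over all genes and 4 over the list alone (camera adjusted p = 0.00276), led by CYBB (1.91 ± 0.398, adjusted p = 0.0132). The largest rises were C1QC (6.19 ± 0.954, adjusted p = 0.000640, with control UMIs in control replicate 1 alone), HMOX1 from 5.32 to 139 CPM (4.58 ± 0.431, adjusted p = 7.27e-09) and CCL2 (2.88 ± 0.595, adjusted p = 0.0131). The largest falls were AGAP2, TP53RK and NFE2L1, calls lost at adjusted p = 0.0504 to 0.474 with 1 guide left out. Without IRF2BP2 replicate 1 or 2, 13 and 18 genes passed. When IRF2BP2 replicate 1 was omitted, adjusted p was 0.177 for HLA-DRB1 (log2 1.53), 0.539 for HLA-DRA (log2 1.93), 0.551 for CYBB (log2 1.37), 0.993 for C1QC (log2 0.55) and 0.867 for CCL2 (log2 1.14). Without IRF2BP2 replicate 2, adjusted p was 0.0627 for HMOX1 (log2 2.85). Kept calls had folds moved over 1.5 times without IRF2BP2 replicate 1 (HMOX1 log2 5.28) and IRF2BP2 replicate 2 (C1QC 7.27, CCL2 3.68).

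Guides against EP300, a histone acetyltransferase, lowered cholesterol synthesis genes, with a count that depended on which of 2 guides was left out. Its guides had deeper cells than any control guide, and few of them, 18 for replicate 1 and 31 for replicate 2. Mitochondrial UMIs were 2.66% and 4.29%, against 4.48 to 7.93% in control guides. 154 genes passed, of which 99 rose and 55 fell, but 0 passed in edgeR without EP300 replicate 1 (567 at an unadjusted p under 0.05, DESeq2 not run) and 539 without replicate 2. The targeted gene, EP300 (ENSG00000100393, chromosome 22, 41092592 to 41180077), was at 35.8 ± 3.94 CPM (SD, n = 2) against 53.5 ± 11 CPM (SD, n = 6) in control guides (log2 change -0.62 ± 0.262, adjusted p = 0.240). ITGAM stood at 0.29 ± 0.361 (adjusted p = 0.784), and at -0.41 against all other guides. Of the cholesterol synthesis genes, 14 of 24 fell over all genes and 23 over the list alone (camera adjusted p = 0.0402), including the farnesyl diphosphate synthase FDPS from 876 to 274 CPM (-1.65 ± 0.317, adjusted p = 0.00376), DHCR7 (-1.83 ± 0.343, adjusted p = 0.00316) and SQLE (-1.28 ± 0.247, adjusted p = 0.00398). Of the interferon-response genes, 15 of 40 rose over all genes and 28 over the list alone, a call lost at camera adjusted p = 0.202, and of the MHC class I genes, 9 of 19 rose over all genes and 11 over the list alone, lost at camera adjusted p = 0.0610. IFITM3 changed by 1.59 ± 0.260 (adjusted p = 0.000687), and the immunoproteasome subunit PSMB9 by 1.49 ± 0.198 (adjusted p = 5.64e-05). The 3 largest falls were the cytotoxic granule gene NKG7 (-2.03 ± 0.374, adjusted p = 0.00291), SLCO4C1 and TMEM189, and the largest rises IFI27, LGALS3BP and IFIT1, the last 5 lost at adjusted p = 0.0504 to 0.994 with 1 guide left out. None of the 17 calls named by the rule was kept with each guide left out in turn. Leaving out EP300 replicate 1 gave adjusted p of 0.819 for FDPS (log2 -1.08), 0.638 for DHCR7 (log2 -1.54), 0.819 for SQLE (log2 -0.77), 0.940 for IFITM3 (log2 0.45), 0.518 for PSMB9 (log2 1.08) and 0.638 for NKG7 (log2 -1.96). Calls held with folds moved over 1.5 times without EP300 replicate 2 (IFITM3 log2 2.23, FDPS -2.68, SQLE -2.21).

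Guides against 3 subunits of Mediator, the coactivator that links transcription factors to RNA polymerase II, gave counts of genes that depended on which of 2 guides was left out. 146 genes passed with MED16 guides (124 rose, 22 fell), 51 with MED23 guides (43 rose, 8 fell) and 84 with MED24 guides (74 rose, 10 fell). Mitochondrial UMIs were 2.20% and 4.70% for MED16 replicate 2 and 3 and 2.44% and 3.88% for MED24 replicate 1 and 3. They were 4.21% and 4.23% for MED23 replicate 1 and 2, against 4.48 to 7.93% in control guides. Some guides of ZFP36L2, FLI1, GFI1 and DOT1L also lay below the control guides. Without MED16 replicate 2, 1 gene passed and without replicate 3, 317. The counts were 23 and 1 without MED23 replicate 1 and 2, and 0 (edgeR, 864 at an unadjusted p under 0.05, DESeq2 not run) and 506 without MED24 replicate 1 and 3. Of 41 monocyte and macrophage genes, 6, 3 and 4 rose over all genes with MED16, MED23 and MED24 guides, and 16, 10 and 14 over the list alone. These list calls were lost at adjusted p = 0.0844, 0.242 and 0.258 with an estimated correlation. The targeted genes were MED16 (ENSG00000175221, chromosome 19, 867963 to 893187), MED23 (ENSG00000112282, chromosome 6, 131573966 to 131628313) and MED24 (ENSG00000008838, chromosome 17, 40019104 to 40054408), with log2 changes of -1.05 ± 0.346 (adjusted p = 0.165), -1.38 ± 0.507 (adjusted p = 0.247) and -0.15 ± 0.451 (adjusted p = 0.947). ITGAM rose with MED23 guides (1.33 ± 0.310, adjusted p = 0.0407) and stood at 0.90 ± 0.317 (adjusted p = 0.162) with MED16 and 1.23 ± 0.377 (adjusted p = 0.136) with MED24 guides. Without MED24 replicate 1 the log2 change was -0.27 for ITGAM and 0.47 for MED24 itself, which was at 0.02 against all other guides. With MED23 replicate 2 left out, adjusted p was 0.720 for ITGAM (log2 0.83). ITGAM reached adjusted p of 0.0600, 0.0557 and 0.0655 without control replicate 3, 4 and 6.

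With MED16 guides the vasodilator peptide gene ADM (3.66 ± 0.638, adjusted p = 0.00156), the secreted glycoprotein gene LGALS3BP (2.69 ± 0.502, adjusted p = 0.00322) and S100A8 (2.42 ± 0.471, adjusted p = 0.00425) rose most. Of the NADPH oxidase genes, 1 of 7 rose over all genes and 3 over the list alone (camera adjusted p = 0.0396), namely CYBA (0.75 ± 0.136, adjusted p = 0.00221). Of the cholesterol synthesis genes, 6 of 24 fell over all genes and 19 over the list alone, a call lost at camera adjusted p = 0.0759, with HMGCS1 at -1.47 ± 0.341 (adjusted p = 0.0194) and MVD at -1.59 ± 0.357 (adjusted p = 0.0156). Dropping MED16 replicate 2 gave adjusted p of 0.874 for ADM (log2 1.38), 0.646 for LGALS3BP (log2 1.72), 0.746 for S100A8 (log2 1.29), 0.633 for CYBA (log2 0.53), 0.646 for HMGCS1 (log2 -1.07) and 0.633 for MVD (log2 -1.37). Folds moved over 1.5 times with calls kept without MED16 replicate 3 (ADM log2 4.87, LGALS3BP 3.53, S100A8 3.06, HMGCS1 -2.29). With MED23 guides the prostaglandin D synthase PTGDS (3.19 ± 0.456, adjusted p = 0.000278), the adaptor SAMSN1 (2.53 ± 0.537, adjusted p = 0.0254) and S100A9 (2.39 ± 0.499, adjusted p = 0.0254) rose most. Omitting MED23 replicate 1 gave adjusted p of 0.118 for SAMSN1 (log2 2.68). Removing MED23 replicate 2 gave adjusted p of 0.725 for PTGDS (log2 1.28), 0.437 for SAMSN1 (log2 2.39) and 0.474 for S100A9 (log2 1.92). SAMSN1 and S100A9 each reached adjusted p of 0.0532 without control replicate 6. Kept calls had folds moved over 1.5 times without MED23 replicate 1 (PTGDS log2 4.07). With MED24 guides the lysosomal protease CTSD (2.62 ± 0.406, adjusted p = 0.000598), IFI27 (2.82 ± 0.427, adjusted p = 0.000598) and SERPINA1 (2.96 ± 0.684, adjusted p = 0.0246) rose most, and the metalloproteinase inhibitor TIMP3 fell from 355 to 75.3 CPM (-2.19 ± 0.440, adjusted p = 0.00631). When MED24 replicate 1 was omitted, adjusted p was 0.844 for CTSD (log2 0.60), 0.125 for IFI27 (log2 2.21), 0.573 for SERPINA1 (log2 2.11) and 0.258 for TIMP3 (log2 -1.82). Calls held with folds moved over 1.5 times without MED24 replicate 3 (SERPINA1 log2 3.65, CTSD 3.50, TIMP3 -2.93). The other large falls were NKD2, ALDH1L2 and AKAP1 with MED16 (lost at adjusted p = 0.0507 to 0.646 with 1 guide left out), ZNF670, SAAL1 and HES6 with MED23 (0.0519 to 0.474), and CKAP2L and MFSD14C with MED24 (0.0605 to 0.390). No call named by the rule for these 3 targets was kept with each guide left out in turn.

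Guides against STK11, the kinase LKB1 that activates AMPK, gave 69 genes past the threshold, of which 66 rose and 3 fell. The largest rises were the matrix protein gene THBS1 (6.09 ± 1.18, adjusted p = 0.00494), AKR1C2 (5.47 ± 0.924, adjusted p = 0.00162) and S100A12 (3.47 ± 0.874, adjusted p = 0.0475), and the largest falls were GNL2 (-1.53 ± 0.379, adjusted p = 0.0419), CCNB1IP1 (-1.32 ± 0.303, adjusted p = 0.0230) and the chaperonin subunit CCT8 (-0.69 ± 0.171, adjusted p = 0.0394). The targeted gene, STK11 (ENSG00000118046, chromosome 19, 1205778 to 1228431), was at 9.62 ± 6.05 CPM (SD, n = 2) against 28.3 ± 5.63 CPM (SD, n = 6) in control guides (log2 change -1.14 ± 0.468, adjusted p = 0.388, -2.31 to -0.95 with 1 guide left out). ITGAM stood at 0.57 ± 0.354 (adjusted p = 0.684), at -0.0850 without STK11 replicate 2 and at -0.15 against all other guides. Without STK11 replicate 3, which had 19 cells and 2.16% mitochondrial UMIs, 1 gene passed, and without replicate 2, 138. Without STK11 replicate 2, adjusted p was 0.422 for GNL2 (log2 -1.83), 0.122 for CCNB1IP1 (log2 -2.26) and 0.344 for CCT8 (log2 -0.65). Leaving out STK11 replicate 3 gave adjusted p of 0.692 for THBS1 (log2 4.59), 1 for AKR1C2 (log2 0.0550), 0.940 for S100A12 (log2 1.48), 0.624 for GNL2 (log2 -1.46), 0.624 for CCNB1IP1 (log2 -1.13) and 0.624 for CCT8 (log2 -0.72). S100A12 reached adjusted p of 0.0667, 0.0603, 0.0642, 0.0846 and 0.0852 without control replicate 2, 3, 4, 5 and 6. GNL2 reached adjusted p of 0.0507, 0.0628, 0.0623 and 0.0637 without control replicate 2, 3, 4 and 5. CCT8 reached adjusted p of 0.0818 and 0.0706 without control replicate 3 and 6. Folds moved over 1.5 times with calls kept without STK11 replicate 2 (THBS1 log2 7.44, AKR1C2 7.06, S100A12 4.89), control replicate 1 (S100A12 4.08) and control replicate 5 (THBS1 6.82).

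Guides against CD14, the lipopolysaccharide coreceptor, changed no gene past the threshold. edgeR called 0 genes, with 286 at an unadjusted p under 0.05, and DESeq2 also called 0. Without the filter on low counts, edgeR called 10. The targeted gene, CD14 (ENSG00000170458, chromosome 5, 140631732 to 140633701), was at 8.15 ± 6.48 CPM (SD, n = 2) against 13.3 ± 13.6 CPM (SD, n = 6) in control guides (log2 change -0.72 ± 1.05, adjusted p = 1, -2.14 to -0.0810 with 1 guide left out), and 1 of its 2 guide features carries the prefix sh in the files. ITGAM stood at -0.12 ± 0.323 (adjusted p = 1), and at 0.0530 without CD14 replicate 1. For GFI1B, with 1 usable guide and no test, ITGAM was at 45.2 CPM.

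Surface CD11b, an integrin of mature myeloid cells, was read by its antibody tag. The control guides averaged 102 ± 26.9 CD11b UMIs per cell (SD, n = 6). Means with SD were 322 ± 32.5 for DOT1L (n = 3, fold 3.23 on the log2 scale of guide means, exact p = 0.0238), 215 ± 32.2 for GSE1 (n = 3, fold 2.15, exact p = 0.0238), 173 ± 42 for ZFP36L2 (n = 3, fold 1.70, exact p = 0.0714) and 146 ± 8.72 for FLI1 (n = 3, fold 1.47, exact p = 0.0476). Of the targets with 2 guides, MED24 had a fold of 3.65, MED23 2.92, GFI1 2.31, MED16 2.29, EP300 1.95, IRF2BP2 1.79, STK11 1.35 and CD14 1.13. Single guides moved some folds: without replicate 2 or 3 of MED16 they were 1.38 and 3.78, without replicate 1 or 3 of MED24 2.26 and 5.89, and without replicate 1 or 2 of EP300 1.40 and 2.71. None passed after adjustment over 12 targets and both antibodies (exact permutation of guides, smallest adjusted p = 0.214). There, 2 guides against 6 cannot give p under 0.0714 and 3 against 6 not under 0.0238. No target could thus pass, so the lack of calls does not speak against a difference. Against all other guides the log2 difference of CD11b turned negative for ZFP36L2, FLI1, STK11 and CD14, without passing. For CD14 it was -0.0800 without CD14 replicate 2. The single GFI1B guide had 118 UMIs per cell. Guides of 1 target resembled each other more than guides of other targets (permutation of 34 guides among 13 groups, F = 5.31, adjusted p = 0.00074).

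Cells with high CD11b (over 341 UMIs, the 95th percentile of control cells) made up 4.41% ± 3.16 of a control guide (SD, n = 6). The mean share was 35.5% for MED24, 27.6% for MED16, 23.9% for MED23, 21.9% for DOT1L, 19.1% for GFI1, 18.3% for EP300, 15.2% for GSE1, 11.6% for IRF2BP2, 10.5% for ZFP36L2, 9.64% for FLI1, 9.29% for STK11 and 5.35% for CD14. The 2 guides stood at 17.6% and 53.3% for MED24, 7.55% and 47.6% for MED16 and 3.23% and 33.3% for EP300. So 1 guide moved these means. No target passed (exact permutation of guides, smallest adjusted p = 0.122). CD16, the Fc receptor III of monocytes and neutrophils, averaged 18.8 ± 8.14 UMIs per cell in control guides (SD, n = 6) and 18.8 ± 4.28 in ZFP36L2 guides (SD, n = 3, exact p = 0.809). Its log2 difference was negative without ZFP36L2 replicate 5 (-0.11) or control replicate 2 (-0.00257). It was also negative at 3 UMIs and 60% (-0.32) and per 10000 RNA UMIs (-0.40). Non-targeting guide 19 stood apart at 35.4 UMIs. Target means ran from 14.7 for EP300 to 25.8 for GSE1, whose replicate 3 had 41.9 (17.2 capped). Cell medians were 14 to 16 in every group, so the means may show background. The smallest adjusted p was 0.312 (exact permutation). Guides of 1 target did not stand apart (F = 0.623, permutation adjusted p = 0.814).

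**Figure D3:**
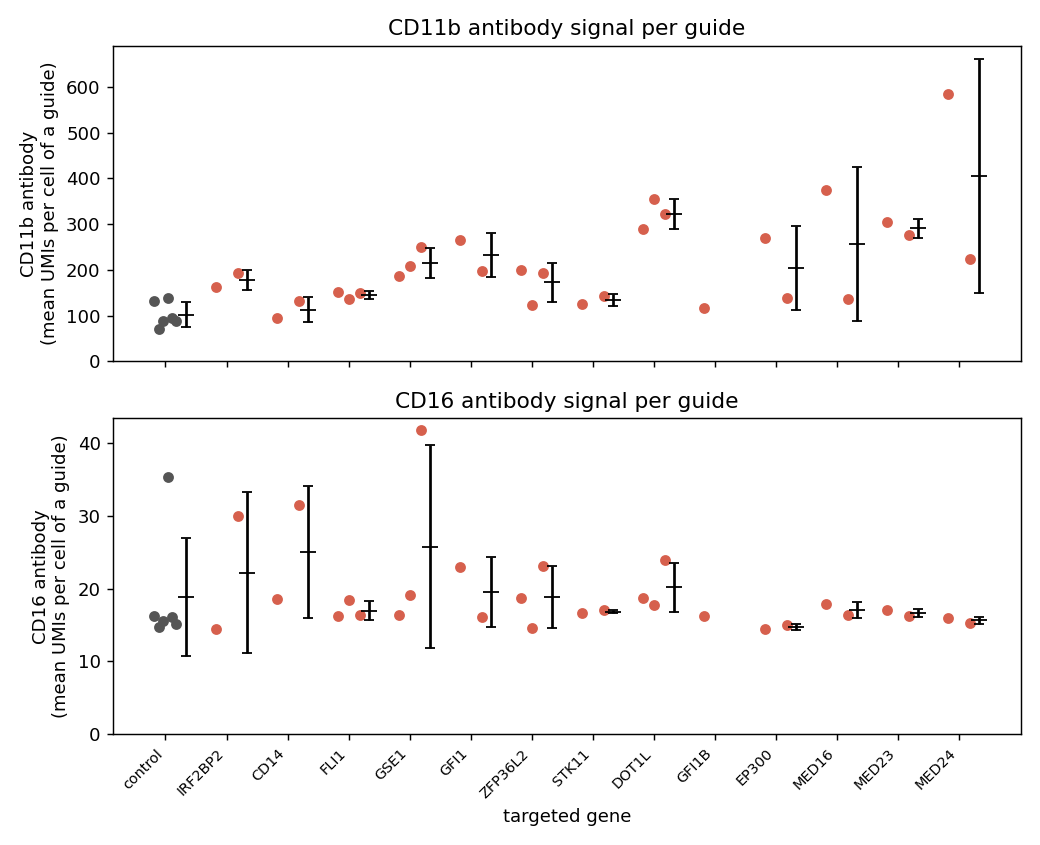
Mean antibody UMIs per cell of each guide (y axes, linear from 0) for CD11b and CD16 by targeted gene (x axis), points being guides and bars the mean with SD where there were at least 2 guides. The 3 DOT1L guides lie between 290 and 354 CD11b UMIs, above all 6 control guides (70.6 to 139), while 1 control guide stands at 35.4 CD16 UMIs.

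The CD11b antibody signal followed ITGAM RNA across targets. Over 13 group means, controls included, Pearson's r was 0.858 (permutation p = 0.000210, adjusted p = 0.000420) and Spearman's rho 0.824 (permutation p = 0.000880, adjusted p = 0.00176). Without DOT1L and CD14, the groups farthest from the median of ITGAM, r was 0.805 and rho 0.755. Over 34 guides r was 0.820 and rho 0.746, and with target means removed r was 0.643 (permutation p = 0.0288) and rho 0.385 (permutation p = 0.144). These 4 relations were the whole family.

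**Figure D4:**
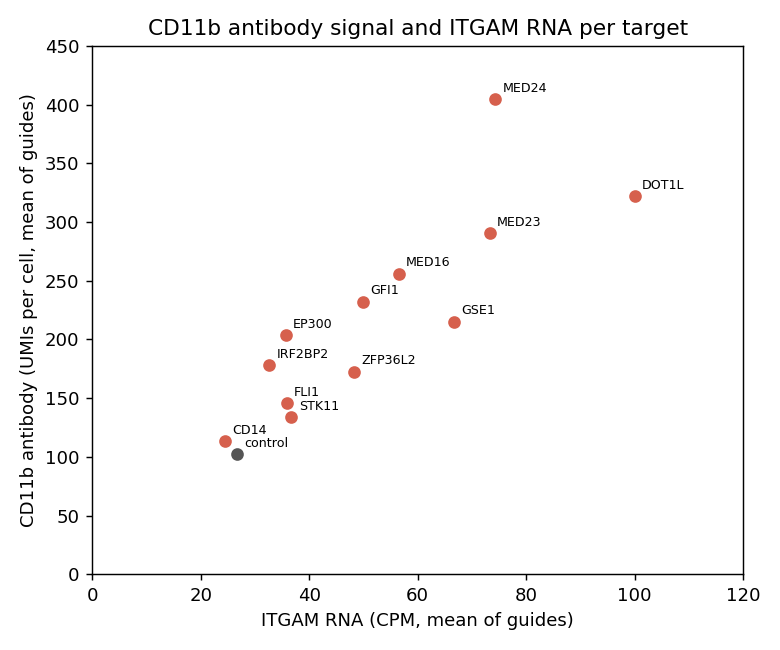
Mean CD11b antibody UMIs per cell (y axis) against mean ITGAM RNA in CPM (x axis), each point the mean over the guides of 1 targeted gene or of the control guides. Control guides lie at 26.6 CPM and 102 UMIs, and the ZFP36L2 guides at 48.3 CPM and 173 UMIs.

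The response to ZFP36L2 guides was set against that to each other target across 10282 genes, which are not independent replicates. All comparisons shared the 6 control guides, so the correlation of log2 changes expected with no effect was simulated, and the control guides were also split between the comparisons. The correlation, with the simulated value and then that with split controls in parentheses, was 0.605 for FLI1 (0.394, 0.407), 0.535 for GFI1 (0.266, 0.379), 0.429 for DOT1L (0.198, 0.328), 0.477 for GSE1 (0.4, 0.241), 0.427 for IRF2BP2 (0.237, 0.28) and 0.397 for MED16 (0.228, 0.269). It was 0.375 for MED24 (0.178, 0.266), 0.302 for MED23 (0.216, 0.175), 0.267 for EP300 (0.234, 0.147), 0.255 for STK11 (0.179, 0.15) and 0.238 for CD14 (0.273, 0.053). The covariance was 0.133 for DOT1L against a simulated 0.0219, 0.0942 against 0.0222 for FLI1 and 0.0312 against 0.0217 for CD14. Genes that rose with both ZFP36L2 and FLI1 guides numbered 135, where independent lists would share 16.4, and those that rose with both ZFP36L2 and DOT1L guides 144, where independent lists would share 29.4. Part of either excess may come from the shared controls.

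Markers of other cell types were summed for each guide. Levels in control guides (SD, n = 6) against ZFP36L2 guides (SD, n = 3) were 63.5 ± 17.2 against 67.6 ± 8.06 CPM for T and NK cells (most abundant NKG7), 29.5 ± 5.17 against 30.3 ± 2.20 CPM for B and plasma cells (most abundant CD79B) and 3.81 ± 1.46 against 2.97 ± 2.09 CPM for erythroid and megakaryocytic cells (most abundant ITGA2B). They were 29.9 ± 3.94 against 24.5 ± 5.20 CPM for mast cells and basophils (most abundant GATA2), 42.8 ± 10.8 against 39.9 ± 6.56 CPM for dendritic cells (most abundant IL3RA) and 5.97 ± 3.05 against 3.09 ± 1.61 CPM for epithelial and stromal cells (most abundant KRT8). In other targets the T and NK cell sum was 166 ± 128 CPM for STK11, 163 ± 28.1 for DOT1L, 105 ± 14.3 for GSE1, 98.6 ± 44.8 for GFI1, 29.3 ± 17 for MED24, 27.3 ± 7.35 for FLI1 and 15.1 ± 1.36 for EP300 (SD). The mast cell and basophil sum was 19.6 ± 6.27 CPM for FLI1, 15.9 ± 5.40 for MED23, 12.4 ± 5.83 for IRF2BP2 and 9.28 ± 9.18 for MED16 (SD). The sums were not tested. Only 3 genes of the T and NK cell list, 2 of B and plasma cells, 1 of mast cells and basophils and 2 of dendritic cells were abundant enough for a test, and 0 of the erythroid and megakaryocytic and 0 of the epithelial and stromal list. None of those tested passed with ZFP36L2 guides in edgeR.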

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

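The CD15 and CD14 tags, the tests of binding by any or every antibody and of FUT4 and FUT7 RNA, the restriction to cells with 10000 to 20000 RNA UMIs, and the count of splits for ZFP36L2 were chosen after the result was seen. The CD15 tag, which the labels do not name, was higher in ZFP36L2 guides, at 553 ± 96.8 UMIs per cell (SD, n = 3) against 236 ± 25.9 in control guides (SD, n = 6), a fold of 2.33, with 3 of 3 guides above every control guide. The two-sided exact permutation p against the control guides, the comparator fixed beforehand, was 0.0238, the smallest this design can give, and did not pass (adjusted p = 0.571). No target could pass this adjusted test against the control guides. Against all other guides the exact permutation p was 0.000306 (adjusted p = 0.00733). The tables argue against larger cells, since the fold was 2.20 in cells with 10000 to 20000 RNA UMIs. They also argue against more FUT4 RNA, a fucosyltransferase that makes the CD15 epitope, at a log2 change of -0.17 ± 0.184 (edgeR adjusted p = 0.665). RNA of a second fucosyltransferase, FUT7, fell (-0.85 ± 0.265, adjusted p = 0.0419). That adjusted p rose to 0.195 and 0.151 without ZFP36L2 replicate 3 and 5, and to 0.0549, 0.0575, 0.0592 and 0.0592 without control replicate 2, 3, 5 and 6. An equal rise of every antibody, a test added once the next one had left its question open, is argued against as the whole cause. Within guides CD15 rose over CD14 by a mean log2 of 1.04 and over CD16 by 1.17, with 3 of 3 ZFP36L2 guides above every control guide for both (exact permutation p = 0.0238 each, unadjusted). Cells that bind any antibody more, as a part of the rise, cannot be told apart from a rise of CD15 alone. The larger of the CD16 and CD14 log2 rises was 0.148 times that of CD15, but 0.260 and 0.265 times without ZFP36L2 replicate 3 and control replicate 4, over the bound of 0.25, and CD11b rose by 0.629 times as much. A biological difference made by these guides stays open as untested.

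ZFP36L2 RNA was higher in ZFP36L2 guides (log2 change 0.63 ± 0.145). RLE size factors gave 0.61 but, like TMM, assume most genes unchanged, so scaling stays open. ZFP36L1, a paralog, gained 79.0 CPM beside 259 CPM for ZFP36L2, which does not count misassigned reads. A rise in any maturing cell stays open. The mean log2 change over DOT1L, GFI1 and FLI1 guides was 0.22, between the bounds set for either answer. The call was lost without ZFP36L2 replicate 5 (0.56) and at 10000 to 20000 RNA UMIs (0.42).

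The genes called in ZFP36L2 guides may reflect larger cells. In cells with 10000 to 20000 RNA UMIs their median signed log2 change was 97.8% of that in all cells. Of 667 measured genes 654 kept their direction, over 61 ZFP36L2 and 256 control cells. These cells were among those that chose the genes and their signs, so both values argue only weakly against larger cells. In this range 185 genes passed, 139 of them among the 735 called in all cells. For the 4 targets with 3 guides, 1 of 84 splits of target and control guides, the real one, gave as many genes. No smaller share is possible with this design. Every other split left at least 1 target guide among the controls, which widens the spread there and lowers the count. The splits therefore cannot exclude chance in the grouping of guides. The counts were 735 genes for ZFP36L2 against at most 1 in any other split, 471 genes for FLI1 against at most 3, 57 genes for GSE1 against at most 1 and 939 genes for DOT1L against at most 118.

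Single control guides stood far from the other 5 for 8 of 32 measures examined, where chance gives about 5% of groups. Non-targeting guide 19 had 35.4 CD16 antibody UMIs per cell (16.6 capped), the others 14.7 to 16.2. It had 108 CD14 antibody UMIs (63.5 capped), the others 49 to 64.5. Its highest cells raised both. For ZFP36L2 RNA (CPM) it was non-targeting guide 17 at 369, the others 460 to 514. For EGLN3 it was non-targeting guide 18 at 9.65, the others 1.81 to 4.71 CPM, and for HMOX1 non-targeting guide 6 at 12.7, the others 2.46 to 5.20 CPM. For ANKRD18A it was non-targeting guide 17 at 23.4, the others 7.97 to 10.2 CPM, and for FUT4 Rosa26 guide 2 at 59.1, the others 41 to 43 CPM. FCGR3A had 0.453 CPM in non-targeting guide 6, from 1 UMI, and 0 UMIs in the other 5 control guides.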

How the results depend on the processing

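Alternatives with control guides of 1 kind, with cells of 10000 to 20000 RNA UMIs, with medians or capped values, and with the CD15 and CD14 tags were chosen after the data were seen. No paired analysis was possible because a guide replicate has no partner among guides of another target. Where a left-out guide leaves 1, that guide is assumed to vary like those of the other targets. With RLE size factors no count of genes moved by more than 1.5 times, and assignment at 10 UMIs and 90% likewise moved none of those it could test. The named genes kept their direction in all but 13 alternative values, a weak test since most were chosen by p or direction. Calls were lost in 432 values of other settings and 293 with a guide left out. Simulation recovered 25.4% of 2-fold changes for MED24, with fewer guides and cells than ZFP36L2. Of 10282 genes DESeq2 gave no adjusted p, and so no call, for 8571 with MED23, 7176 with STK11, 6379 with MED16, 6180 with EP300 and with MED24, 4186 with FLI1 and with IRF2BP2, 2592 with ZFP36L2 and 200 with GFI1 guides. For folds not reported here, a choice made after their signs were seen to depend on the setting, 31 of 161 alternative values changed sign for the CD14 tag in other targets, 15 of 177 for the CD15 tag, 38 of 216 for FCGR3A RNA and 5 of 150 for ZFP36L2 RNA in targets other than ZFP36L2, DOT1L, GFI1 and FLI1.

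The number of genes past the threshold moved by over 1.5 times for some targets, and the cause was not tested. Against all other guides, changes shared with other targets can lower it. With DESeq2 it was 34 for GSE1, 134 for STK11, 316 for EP300, 291 for MED16, 125 for MED23 and 210 for MED24. With no filter on low counts it was 243 for IRF2BP2, 10 for CD14, 153 for GSE1, 310 for GFI1, 152 for STK11, 262 for EP300, 331 for MED16, 194 for MED23 and 195 for MED24. With assignment at 3 UMIs and 60% it was 179 for IRF2BP2, 279 for GFI1, 168 for STK11, 410 for EP300 and 265 for MED16. With no cell filter it was 402 for EP300 and 95 for MED23. Without the top 5% of cells by UMIs it was 156 for IRF2BP2, 106 for STK11, 278 for MED16 and 97 for MED23. With only the guides of the target and the controls in the fit it was 197 for IRF2BP2, 803 for FLI1, 143 for GSE1, 304 for GFI1, 1177 for ZFP36L2, 173 for MED23 and 18 for MED24. Against all other guides it was 1 for IRF2BP2, 21 for FLI1, 2 for GSE1, 5 for GFI1, 131 for ZFP36L2, 7 for STK11, 487 for DOT1L, 12 for EP300, 0 for MED16, 2 for MED23 and 1 for MED24. Against non-targeting guides alone it was 15 for IRF2BP2, 156 for FLI1, 15 for GSE1, 94 for GFI1, 309 for ZFP36L2, 26 for STK11, 58 for EP300, 45 for MED16, 7 for MED23 and 37 for MED24. Against Rosa26 guides alone it was 10 for IRF2BP2, 107 for FLI1, 11 for GSE1, 91 for GFI1, 216 for ZFP36L2, 17 for STK11, 10 for EP300, 8 for MED16, 2 for MED23 and 4 for MED24. In cells with 10000 to 20000 RNA UMIs it was 185 for ZFP36L2. The 0 for MED16 was edgeR's, with 731 genes at an unadjusted p under 0.05. With each guide left out in turn the number ran from 0 to 1 for CD14, from 256 to 978 for DOT1L, from 0 to 539 for EP300, from 163 to 477 for FLI1, from 55 to 186 for GFI1, from 19 to 46 for GSE1, from 13 to 120 for IRF2BP2, from 1 to 317 for MED16, from 1 to 50 for MED23, from 0 to 506 for MED24, from 1 to 138 for STK11 and from 307 to 676 for ZFP36L2. The lowest counts of 0 for EP300 and MED24 were edgeR's, and DESeq2 was not run on them.

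The number of gene lists past the threshold fell with an estimated correlation in camera to 2 for IRF2BP2, 0 for CD14, 2 for FLI1, 0 for GSE1, 2 for GFI1, 4 for ZFP36L2, 0 for STK11, 6 for DOT1L, 1 for EP300, 1 for MED16, 0 for MED23 and 0 for MED24. With fry, which asks whether the genes of a list move one way and not whether they differ from other genes, it was 6 for IRF2BP2, 0 for CD14, 4 for GSE1, 8 for GFI1, 10 for ZFP36L2, 0 for STK11, 3 for EP300, 7 for MED16, 2 for MED23 and 3 for MED24.

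Differences in antibody signal (log2) changed sign for some targets, none of them past the threshold in either direction, and the cause was not tested. The CD11b tag was -0.18 for CD14 with assignment at 3 UMIs and 60% and -0.0112 taken as medians over cells. Against all other guides it was -0.70 for CD14, -0.30 for FLI1, -0.0695 for ZFP36L2 and -0.43 for STK11. With assignment at 3 UMIs and 60% the CD16 tag was -0.26 for IRF2BP2, -0.10 for CD14, -0.13 for GSE1, -0.43 for GFI1, -0.32 for ZFP36L2 and -0.36 for DOT1L. With assignment at 10 UMIs and 90% the CD16 tag was 0.17 for FLI1, 0.11 for STK11 and 0.0379 for MED23. Taken as the mean of log2(UMIs + 1) the CD16 tag was 0.0161 for FLI1, 0.10 for STK11, 0.0313 for MED16, 0.0631 for MED23 and 0.0420 for MED24. Counted per 10000 RNA UMIs the CD16 tag was -0.00548 for GFI1, -0.40 for ZFP36L2 and 0.42 for STK11. With no cell filter the CD16 tag was -0.0326 for DOT1L. Taken as medians over cells the CD16 tag was 0.0664 for FLI1, 0.11 for STK11, 0.0166 for MED16, 0.00969 for MED23 and 0.0664 for MED24. With cells capped at the 99th percentile the CD16 tag was 0.0518 for FLI1, 0.10 for STK11, 0.10 for MED16 and 0.0837 for MED23. The CD14 tag was -0.31 for CD14 and -0.0690 for ZFP36L2 with assignment at 3 UMIs and 60%. It was -0.27 for ZFP36L2 per 10000 RNA UMIs and -0.0334 for CD14 against all other guides. With each guide left out, the CD11b tag ran from -0.0800 to 0.42 for CD14. The CD16 tag then ran from -0.13 to 0.13 for FLI1, -0.15 to 0.36 for GFI1 and -0.00823 to 0.67 for GSE1. It ran from -0.31 to 0.75 for IRF2BP2, -0.13 to 0.14 for MED16 and -0.15 to 0.10 for MED23. It ran from -0.25 to 0.00912 for MED24, -0.14 to 0.12 for STK11 and -0.11 to 0.25 for ZFP36L2. The CD14 tag then ran from -0.0614 to 0.26 for CD14. At the 99th percentile the share of high CD11b cells of STK11 differed from that of control guides by -0.0923 percentage points.

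RNA log2 changes reversed for a few named genes, none past the threshold after reversal, and the cause was not tested. Against all other guides they were -0.49 for ITGAM in IRF2BP2 guides, -0.39 for ITGAM in FLI1 guides, -0.0270 for HLA-DRB1 in ZFP36L2 guides, -0.21 for HLA-DRA in ZFP36L2 guides, -0.0890 for HLA-DPA1 in ZFP36L2 guides, -0.15 for ITGAM in STK11 guides, -0.41 for ITGAM in EP300 guides and 0.0230 for MED24 in MED24 guides. In cells with 10000 to 20000 RNA UMIs they were 0.0910 for FUT4 in ZFP36L2 guides. Without the top 5% of cells by UMIs they were -0.0310 for ITGAM in EP300 guides. With each guide left out the log2 change ran from -0.53 to 0.0530 for ITGAM in CD14 guides, from -0.27 to 2.13 for ITGAM in MED24 guides, from -0.0850 to 0.71 for ITGAM in STK11 guides, from -0.00400 to 0.26 for ZFP36L2 in DOT1L guides and from -2.26 to 0.47 for MED24 in MED24 guides. That of ZFP36L2 in its own guides ran from 0.56 to 0.71, its call lost without replicate 5. It was also lost against Rosa26 guides alone (0.58) and at 10000 to 20000 RNA UMIs (0.42), with fewer guides or cells.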

Other observations

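The comparison of gene lists between targets and the levels of added genes were chosen after the result was seen. The list of interferon-response (antiviral) genes was called higher at the preset correlation for 8 targets besides ZFP36L2, FLI1 and EP300. None of these calls held with an estimated correlation. Of 40 members the number that rose over all genes, with that over the list alone and the camera adjusted p with an estimated correlation in parentheses, was 25 for DOT1L (29, 0.0740), 14 for MED16 (28, 0.0831), 12 for MED24 (22, 0.199), 7 for IRF2BP2 (26, 0.0755) and 7 for STK11 (22, 0.198). It was 2 for GFI1 (16, 0.313), 2 for GSE1 (2, 0.344) and 2 for MED23 (11, 0.242), and 0 of 40 for CD14 in edgeR. Differences between targets were not tested.

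Primary granule genes, which encode proteases and peroxidase of immature granulocytes and monocytes, fell with DOT1L guides, 7 of 14 measured members over all genes and 8 over the list alone (camera adjusted p = 0.0705). Mitochondrially encoded genes fell in 1 of 13 members with MED16 guides and 13 over the list alone (camera adjusted p = 0.0831), and in 0 with MED24 guides and 13 over the list alone (camera adjusted p = 0.149). In ZFP36L2 guides, RNA of CD14, the lipopolysaccharide coreceptor, rose from 13.3 to 58.1 CPM (log2 change 1.86 ± 0.535, edgeR adjusted p = 0.0261), and RNA of ZFP36L1, a paralog that also binds AU-rich elements, rose from 58.3 to 137 CPM (log2 change 1.11 ± 0.341, adjusted p = 0.0408). Without ZFP36L2 replicate 2, adjusted p was 0.161 for CD14 and 0.102 for ZFP36L1. Leaving out ZFP36L2 replicate 3 gave adjusted p of 0.0534 for CD14 and 0.0849 for ZFP36L1. With ZFP36L2 replicate 5 left out, adjusted p was 0.0672 for CD14 and 0.169 for ZFP36L1. CD14 reached adjusted p of 0.0586, 0.0504 and 0.0610 without control replicate 4, 5 and 6. ZFP36L1 reached adjusted p of 0.0616, 0.0703 and 0.0844 without control replicate 2, 3 and 6. Calls held with folds moved over 1.5 times without control replicate 1 (CD14 log2 2.50). These rises were not particular to ZFP36L2 guides. ZFP36L1 RNA also passed with IRF2BP2 (1.87 ± 0.403, adjusted p = 0.0157, 0.0529 to 0.472 where lost without 1 guide), FLI1 (1.13 ± 0.333, adjusted p = 0.0410, 0.0526 to 0.175 where lost without 1 guide) and DOT1L guides (1.40 ± 0.409, adjusted p = 0.0232, 0.573 (log2 0.80) without DOT1L replicate 1), and CD14 RNA with GFI1 (2.49 ± 0.631, adjusted p = 0.0275, 0.0502 to 0.689 where lost without 1 guide) and DOT1L guides (3.67 ± 0.557, adjusted p = 1.79e-05, kept without each guide).

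The CD14 tag averaged 68.8 ± 10.7 UMIs per cell in CD14 guides (SD, n = 2), 73.5 ± 14 in ZFP36L2 guides (SD, n = 3) and 66.3 ± 21.4 in control guides (SD, n = 6). The exact permutation p was 0.714 for CD14 (adjusted p = 0.929) and 0.524 for ZFP36L2 (adjusted p = 0.786). Guides of 1 target resembled each other more than guides of other targets for CD15 (permutation of 34 guides, F = 6.33, adjusted p = 0.00106) and did not for CD14 (F = 0.99, permutation adjusted p = 0.474).

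Rosa26 guides against non-targeting guides gave 0 genes in edgeR, with 175 of 10282 at an unadjusted p under 0.05, and DESeq2 was not run on that contrast.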
